A study of Mus musculus with 6 samples.

How the data were processed

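RNA from mouse haematopoietic stem cells was measured on 6 one-colour Illumina bead arrays, 3 of wt cells and 3 of cells labelled Matn4-/-. Per the labels' protocols, bone marrow of both donors was mixed in equal parts, the mixture was given to lethally irradiated recipients (2 doses of 500 rad), and stem cells were sorted by flow cytometry 4 weeks later as LSK (lineage negative, Sca-1 and Kit positive), CD150 positive and CD48 negative cells. The wt donor carried the CD45.1 and CD45.2 alleles of Ptprc, the Matn4-/- donor CD45.2 alone and the recipients CD45.1. The labels give female C57/BL6 mice aged 12 weeks. RNA was amplified from 2.5 ng with an isothermal whole-transcript kit and labelled with biotin, per the labels' protocols. The design text calls the 3 arrays of each genotype biological replicates without saying whether they come from separate recipients. The number of arrays limits the precision of every value.

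The deposited value table holds 1 intensity per probe and array on a linear scale. The authors' normalization and background treatment are not given in the sources used here. The column medians of 118.0, 118.1, 118.8, 120.4, 118.1 and 119.7 (wt replicates 1 to 3, then Matn4-/- replicates 1 to 3) show that the arrays had been brought to a similar level and that the background was still in the values. A fold change from such values understates the change of dim genes. The 7 probes of Y-linked genes, which female cells lack, lay between 99.8 and 142.2 with a median of 109.3, and a gene that on each array of a group lay at or below the brightest of them on that same array (123.8 to 142.2) is given as a lower bound of its fold, the mean of the brighter group over the mean of those probes. A gene above them on only some arrays keeps its fold with the number of arrays, and for Ctse and Zfp87 a bound against 142.2 is added.

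A second table with non-normalized signals and detection p-values was not used. Its 12 value columns carry names that match no label, so they could not be assigned to samples. The planned starting point had been that table, with background correction, quantile normalization and a filter on detection p. The deposited intensities were tested instead, as the plan provided for such a case. The filter had to be chosen after the files were seen. It kept the brighter 50% of the probes by mean log2 intensity over the 6 arrays, which left 23118 of 46237 probes.

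Of the 46237 probes, 35784 had 1 gene symbol, none had several and 10453 had none in the platform table. Symbols were updated through Entrez identifiers (28620 probes) or unversioned accessions (931 probes), and other probes kept the symbol of the platform table. A symbol was represented by its brightest kept probe, which gave 12765 genes. Joining probes through older symbols was kept as an alternative. That choice was made after both outcomes had been seen. It matters for Ctse, whose direction it decides. The GRCm38.p6 gene table supplied chromosomes, gene order and distances for 21899 symbols. The build behind the array is not given in the sources used here, so no coordinates are printed.

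Values were transformed to log2 and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, genotype as the only term). P-values were adjusted by the Benjamini-Hochberg method over the 12765 genes, with 0.05 as the threshold. Fold changes are given as Matn4-/- over wt on the log2 scale with the standard error of the fit. The 31 gene lists cover cell state, signalling, metabolism, blood lineages and the neighbours of Matn4 and Ptprc. They were fixed before the data were examined, apart from the membership of both lists of all genes within 10 Mb, which follows from the gene table. Lists were tested with camera at its preset correlation, again with an estimated correlation, and with fry. The planned test of both windows was camera. The comparison of shares of genes at an unadjusted p under 0.05 between regions, with Fisher's exact test (two-sided), was added after the data had been seen, as were the gene bins. Windows were set against 10000 random gene sets of the same size and brightness. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 handled tables and plots.

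Genes are named by a rule set beforehand. Matn4, Ptprc and Cxcr4 are always named. Up to 12 genes per direction follow, first those past the threshold whose groups do not overlap, by fold, then those with the smallest p, said not to have passed. Symbols of the Gm, LOC, EG and Rik kinds are left out of that part. At most 2 members are taken from a list that does not pass the test. Gm8355, B2m, Ccndbp1, Lrrc57, Rmdn3, C920004C08Rik, 3110009E18Rik and Mpo were singled out after their values had been seen.

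The fit was tested on simulated data for this comparison, with the 12765 genes and 20 runs. It called 56% of genes shifted by 0.5 on the log2 scale, 96.6% of those shifted by 1 and 99.9% of those shifted by 2, and 5.33% of its calls were unchanged genes. A list shifted by 0.3 was called in 20 of the 20 runs. The simulated data held 200 changed genes besides that list and drew each gene independently of the others. The real fit called 7 genes, and real genes may move together, so these rates need not hold for it.

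Alternatives were the replicate number as a block, each array left out, further background correction and normalization of the deposited values (quantile, normexp with an offset of 50, cyclic loess, median scaling), no filter, the mean of a gene's probes, every probe on its own, trend and robust moderation, array weights, other thresholds and other list tests. Added after the data had been seen were the brightest 11559 probes, probes above the brightest Y-linked probe, the genes outside both windows, lists without chromosomes 1 and 2, an unadjusted p under 0.001 per chromosome and older symbols joined. Stricter detection and slide as a block were not run, since the first needs the unused columns and no source names a slide.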

Results

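The series compares transplanted haematopoietic stem cells of wt mice with those of mice lacking Matn4, which encodes matrilin-4, an adapter protein of the extracellular matrix. Both kinds of cell had repopulated the same irradiated hosts for 4 weeks. The question is what loss of Matn4 changes in stem cell expression under that stress. There were 3 arrays per genotype, each with 46237 probes. All 6 arrays showed Xist at 299 to 678 and Y-linked probes at 99.8 to 142, which matches the female sex on the labels.

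Matn4 itself did not separate the groups. Its brightest probe read 282 ± 112 in wt cells and 272 ± 90.5 in cells labelled Matn4-/- (SD, n = 3 each), a log2 fold change of -0.02 ± 0.34 (SE, limma adjusted p = 0.999). The other 2 probes lay near background, at 110 ± 5.74 and 120 ± 4.14 in wt and at 110 ± 7.82 and 123 ± 4.37 in Matn4-/- cells. Whether any of the 3 lies in the deleted part is not given in the sources used here, so these values do not check the labels, and each direction below is that of the arrays labelled Matn4-/-. Ptprc, which encodes the CD45 antigen used to tell the donors apart, read 227 ± 18.8 in wt and 209 ± 16.7 in Matn4-/- cells (log2 -0.12 ± 0.09, adjusted p = 0.991).

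Few expression differences stood between the arrays labelled Matn4-/- and those of wt cells. Of 12765 genes tested, 7 passed the threshold, 6 lower and 1 higher in Matn4-/- cells. Serinc3, a serine incorporator family membrane protein, fell furthest, from 1173 ± 67.4 to 303 ± 67.6 (SD, n = 3 each; log2 -1.97 ± 0.14, limma adjusted p = 0.00227). Ctse, which encodes the aspartic protease cathepsin E, fell from 335 ± 40.6 to 116 ± 11.7 (log2 -1.53 ± 0.11, adjusted p = 0.00227), where it lay above the brightest Y-linked probe of the same array on only 1 of 3 arrays, so its wt level was at least 2.35-fold that of the brightest such probe on any array. Plcb2, a phospholipase C of G protein signalling, fell by 1.08 on the log2 scale (SE 0.10, adjusted p = 0.0063), and Tmem87a, a transmembrane protein gene, fell by 1.04 (SE 0.09, adjusted p = 0.00601). Rbm12, which encodes an RNA-binding protein, and Wdr73 fell by 0.63 and 0.60, each with an adjusted p of 0.0444. Gm8355, whose kind of symbol lies outside the naming rule, rose from 669 ± 38.7 to 1566 ± 257 (log2 1.22 ± 0.12, adjusted p = 0.0103). In each of the 7, all 3 Matn4-/- arrays lay on one side of all 3 wt arrays.

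**Figure D1:**
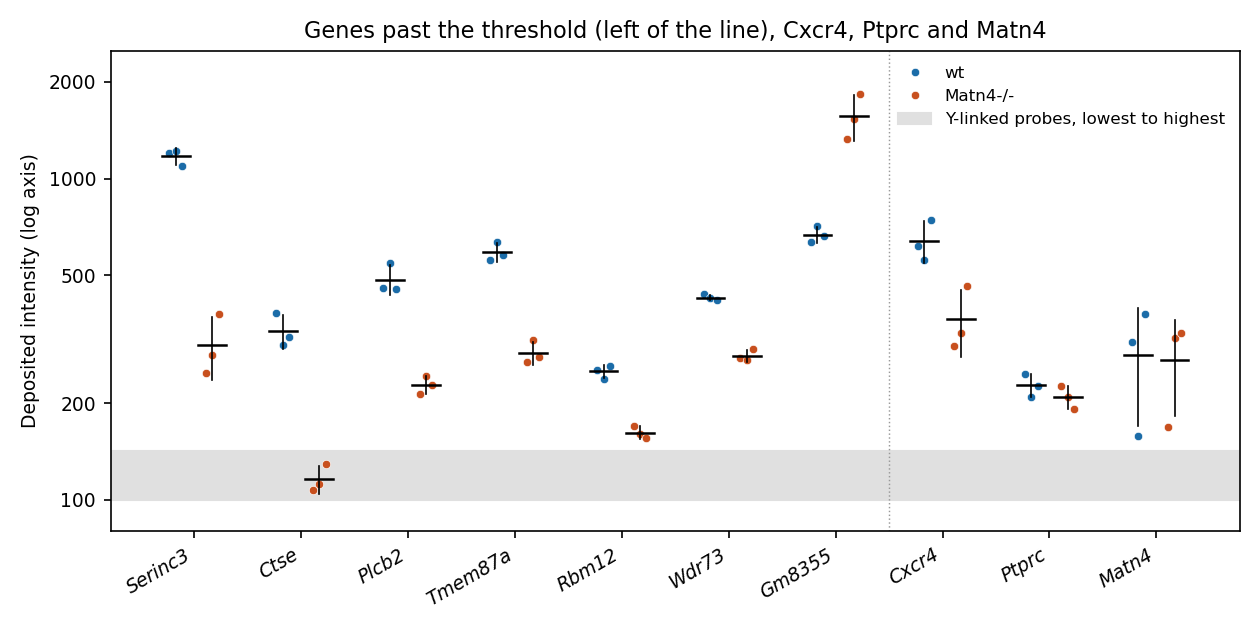
Deposited intensity (log axis) of the brightest probe of each gene on the 3 wt arrays (blue) and the 3 arrays labelled Matn4-/- (orange), with the mean and SD as black lines and the range of Y-linked probes, 99.8 to 142, in grey. The 7 genes left of the dotted line passed the threshold. Cxcr4 read 641 ± 95.6 against 365 ± 86.6, and Ptprc and Matn4 overlapped between the groups.

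Other probes of these genes did not always follow. The second Ctse probe was lower as well and at the level of Y-linked probes on all 3 Matn4-/- arrays (at least 1.34-fold higher in wt), whereas a probe listed under the clone name C920004C08Rik, which the gene table places at Ctse, was higher (161 ± 10.1 against 253 ± 44.3, log2 0.63). The second kept Tmem87a probe differed by -0.16, and 3 of the 4 Rbm12 probes were lower with the other at 0.03. Serinc3, Wdr73 and Gm8355 had no other probe. The other Plcb2 probe, left out by the filter, read 113 in both groups. Rbm12 and Wdr73 passed in 5 and 6 of 21 settings tested gene by gene, against 19 for Ctse and 20 for Serinc3. Genes outside the 7 passed in some as well, Wfdc2 in 7, Zfp87 and Dynlrb1 in 3 each and Rn28s1 in 2. Without Matn4-/- replicate 1, Plcb2 and Tmem87a no longer passed and 3 genes did, and without wt replicate 1, 4 did. At an unadjusted p under 0.05 stood 713 genes, 227 higher and 486 lower, where chance gives 638, and the groups did not overlap in 10.5% of genes, where chance gives 10%. Without Matn4-/- replicate 3, 420 were higher and 441 lower, and the split was 338 to 399 with cyclic loess and 170 to 574 with median scaling.

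Cxcr4, the receptor for the niche chemokine CXCL12, read 641 ± 95.6 in wt and 365 ± 86.6 in Matn4-/- cells (log2 -0.83 ± 0.17). It did not pass over all genes (adjusted p = 0.306). In the fixed list of 31 measured genes of CXCR4 signalling, homing and adhesion, 13 were higher and 18 lower, and 2 passed when adjusted over the list alone. These were Cxcr4 and Cd47, the integrin-associated protein (log2 -0.44), each at 0.0157. Cd47 did not pass over all genes (adjusted p = 0.306). The other kept probes that the gene table places at Cd47, under older or clone names, stood at -0.27, -0.40 and -0.55.

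Further genes came close without passing. Among lower values, Wfdc2 (adjusted p = 0.0541) lay at the level of Y-linked probes in Matn4-/- cells, so its wt level was at least 1.68-fold higher. Zfp87 had a log2 fold change of -0.54 (adjusted p = 0.0541) and lay above the Y-linked probes of the same array on 2 of 3 Matn4-/- arrays, with a wt level at least 1.40-fold that of the brightest on any array. A probe under a clone name that the gene table places at Zfp87 went the other way, by 0.11. Dynlrb1, a dynein light chain, had a log2 fold change of -0.99 (adjusted p = 0.0741). Snx5, above those probes on 2 of 3 Matn4-/- arrays, and Clasrp followed with -0.59 and -0.46 (each adjusted p = 0.166), and Pafah1b2, at their level in Matn4-/- cells, was at least 1.33-fold higher in wt (adjusted p = 0.173). Among higher values, Rn28s1, a 28S ribosomal RNA name, had 0.82 (adjusted p = 0.158), Orc3, of the origin recognition complex, 0.69 and Mthfd2, of mitochondrial folate metabolism, 0.46 (both 0.25). Tmem9 and Nupr1 had 0.43 and 0.38, and Ptpn7, at the level of Y-linked probes in wt cells, was at least 1.16-fold higher in Matn4-/- cells (each 0.306). The second kept probe of Snx5 was lower as well, whereas those of Mthfd2, Tmem9 and Pafah1b2 stood at 0.03, 0.06 and -0.09.

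None of the 31 lists passed the camera test, by either correlation, and none passed fry for a shift one way. The smallest camera p was that of the fixed Matn4 neighbours, of which 14 were higher and 27 lower (adjusted p = 0.0577, and adjusted p = 0.795 with an estimated correlation). At an unadjusted camera p under 0.05 stood 4 lists. Fry's test for changes in either direction passed for 7, both neighbour lists and both windows, CXCR4 signalling (adjusted p = 0.00176), ribosomal proteins and T and NK cells (each 0.0354).

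Genes of stem cell identity went both ways, 15 higher and 17 lower of 32, with Pdzk1ip1 at -0.23 and Clec1a at 0.22. Quiescence genes split 11 to 14 of 25, with Nr4a2 at -0.21 (above the Y-linked probes on 1 of 3 Matn4-/- arrays) and Cdkn1a at the level of those probes on all 3 wt arrays and 1 of 3 Matn4-/- arrays. Genes of G1/S and DNA replication split 18 to 18 of 36 (Fen1 -0.26) and those of G2/M and mitosis 22 to 16 of 38 (Pbk 0.29, Cdc25b -0.18). None of these members passed. Interferon response genes were higher in 17 and lower in 21 of 38, with Xaf1 at -0.54 (adjusted p = 0.432, above the Y-linked probes on 2 of 3 Matn4-/- arrays) and Psmb9 at -0.17. Immediate early genes were higher in 8 and lower in 9 of 17, NF-kB genes in 6 and 9 of 15, and p53 targets in 10 and 14 of 24.

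Matrix genes, the class of matrilin-4, were higher in 19 and lower in 8 of 27 (camera adjusted p = 0.424), with Emilin1 at 0.12 and Hspg2 at the level of Y-linked probes on all 3 wt arrays and 2 of 3 Matn4-/- arrays. TGF-beta and BMP genes were higher in 14 and lower in 9 of 23, and Wnt and Notch genes in 13 and 7 of 20. Heat shock and unfolded protein genes split 13 to 16 of 29 (Asns 0.41), MYC targets 16 to 19 of 35 (Cct5 -0.36) and ribosomal proteins 25 to 19 of 44 (Rplp0 -0.37). For G1/S genes, heat shock genes, MYC targets, neutrophil genes and cholesterol genes the mean was below 0 while camera, which compares with all other genes, pointed up. Oxidative phosphorylation split 27 to 23 of 50, glycolysis and hypoxia 14 to 19 of 33 (Pkm -0.39) and cholesterol and lipid synthesis 8 to 8 of 16. Another kept probe of Pkm, under an older symbol, stood at -0.03.

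The lists of mature blood cell markers were among those that did not pass camera. Under alternatives some did, the monocyte list in 3 of 22 settings (lowest camera adjusted p = 0.0172), the mast cell list in 2 (0.0146) and the erythroid list in 1 (0.0402). With an estimated correlation and all arrays, each of these 3 lists had an adjusted p = 0.795. Markers of mast cells, basophils and eosinophils were higher in 9 and lower in 1 of 10, with Fcer1a at 0.27 (above the Y-linked probes on 2 of 3 wt arrays), and those of monocytes, macrophages and dendritic cells in 9 and 7 of 16, with H2-Ab1 at 0.22. T and NK cell markers were higher in 2 and lower in 5 of 7, with Lat at -0.25 and Cd8b1 at -0.21. Each of the 3 lists had a camera adjusted p of 0.247. The other kept probe of Lat stood at -0.04 and the other 2 of H2-Ab1 at -0.05 and 0.09. Erythroid markers split 10 to 8 of 18 (Car1 0.46), neutrophil and granule genes 7 to 9 of 16, platelet genes 7 to 9 of 16, B cell genes 6 to 3 of 9, progenitor genes 8 to 7 of 15 and stromal and endothelial genes 3 to 7 of 10. The mast cell list differed between arrays of one genotype. It stood at -0.32, -0.08 and 0.26 on wt replicates 1 to 3 and at -0.31, -0.02 and 0.47 on Matn4-/- replicates 1 to 3, relative to its mean over the 6 arrays.

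**Figure D2:**
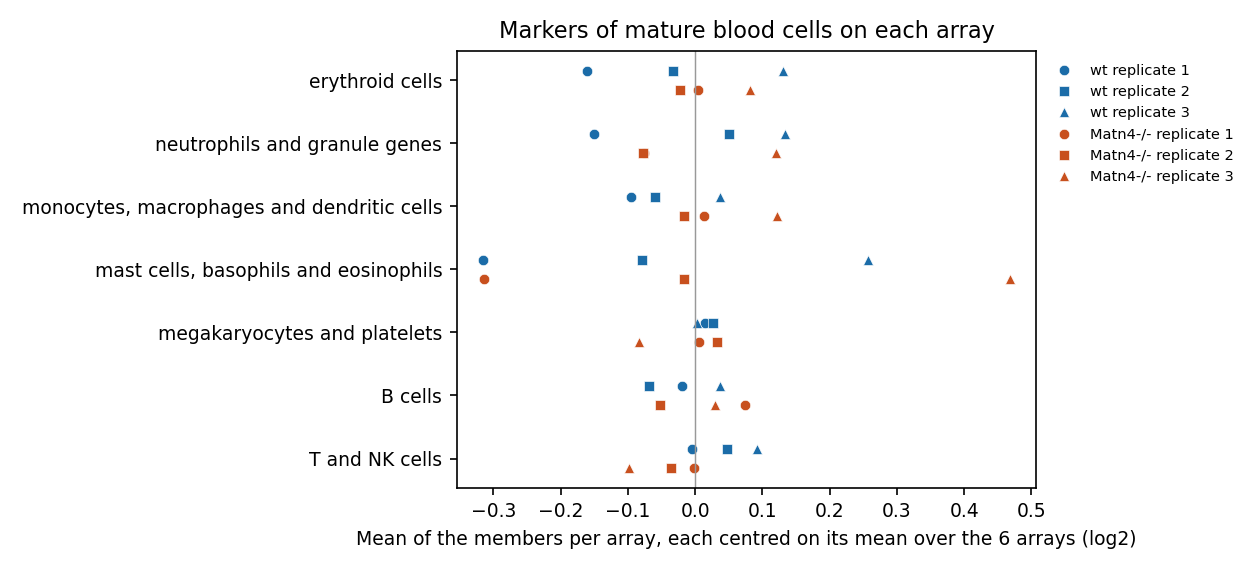
Mean log2 intensity of 7 lists of mature blood cell markers on each array, relative to the list's mean over the 6 arrays, with wt arrays in blue, arrays labelled Matn4-/- in orange and the replicate number as the symbol. The mast cell list spans the widest range, from -0.32 on wt replicate 1 to 0.47 on Matn4-/- replicate 3.

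The genes past the threshold were not spread evenly over the genome. Of the 7, 4 lie on chromosome 2 with Matn4 (Serinc3, Plcb2, Tmem87a and Rbm12) and Ctse lies on chromosome 1 within 10 Mb of Ptprc, as does Cxcr4. The planned camera test passed for neither window, with 73 genes higher and 96 lower of 169 around Matn4 (adjusted p = 0.383) and 37 and 37 of 74 around Ptprc (adjusted p = 0.898), nor for the fixed Ptprc neighbours, 19 and 13 of 32 (adjusted p = 0.442). The shares of genes at a small p, compared after the data were seen, differed. Fisher's test treats genes read on the same arrays as independent, so its intervals may be too narrow and its p-values too small. Within 10 Mb of Matn4, 21 of 169 genes (12.4%) had an unadjusted p under 0.05, 2 higher and 19 lower, against 5.49% of genes elsewhere (odds ratio 2.44, 95% interval 1.46 to 3.9, Fisher's exact p = 0.000533). Within 10 Mb of Ptprc the count was 11 of 74 (14.9%), 4 higher and 7 lower (odds ratio 2.98, 1.41 to 5.74, Fisher's exact p = 0.00255). That ratio was 1.22 without Matn4-/- replicate 3 and 2.08 without wt replicate 3, with Fisher p-values of 0.638 and 0.0906. Each gene of a window was taken under a single name. Values there under other older or clone names, among them C920004C08Rik at Ctse, were counted as elsewhere. Chromosome 2 beyond the window held 51 of 842 genes at that level (odds ratio 1.1, Fisher's exact p = 0.534). Chromosome 2 as a whole did not pass at that level, with 72 of 1011 genes (odds ratio 1.33, adjusted p = 0.365 over 20 chromosomes). At an unadjusted p under 0.001, a level chosen after the data were seen, chromosome 2 held 11 of 1011 genes, each lower, against 28 of 11754 elsewhere (odds ratio 4.61, adjusted p = 0.00308). Without the genes near Matn4 and Ptprc, 3 passed, namely Gm8355, Plcb2 and Tmem87a. Plcb2 and Tmem87a lie on chromosome 2 too. How far any DNA of another strain extends from Matn4 is not given in the sources used here, so the 10 Mb limit does not exclude it there.

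**Figure D3:**
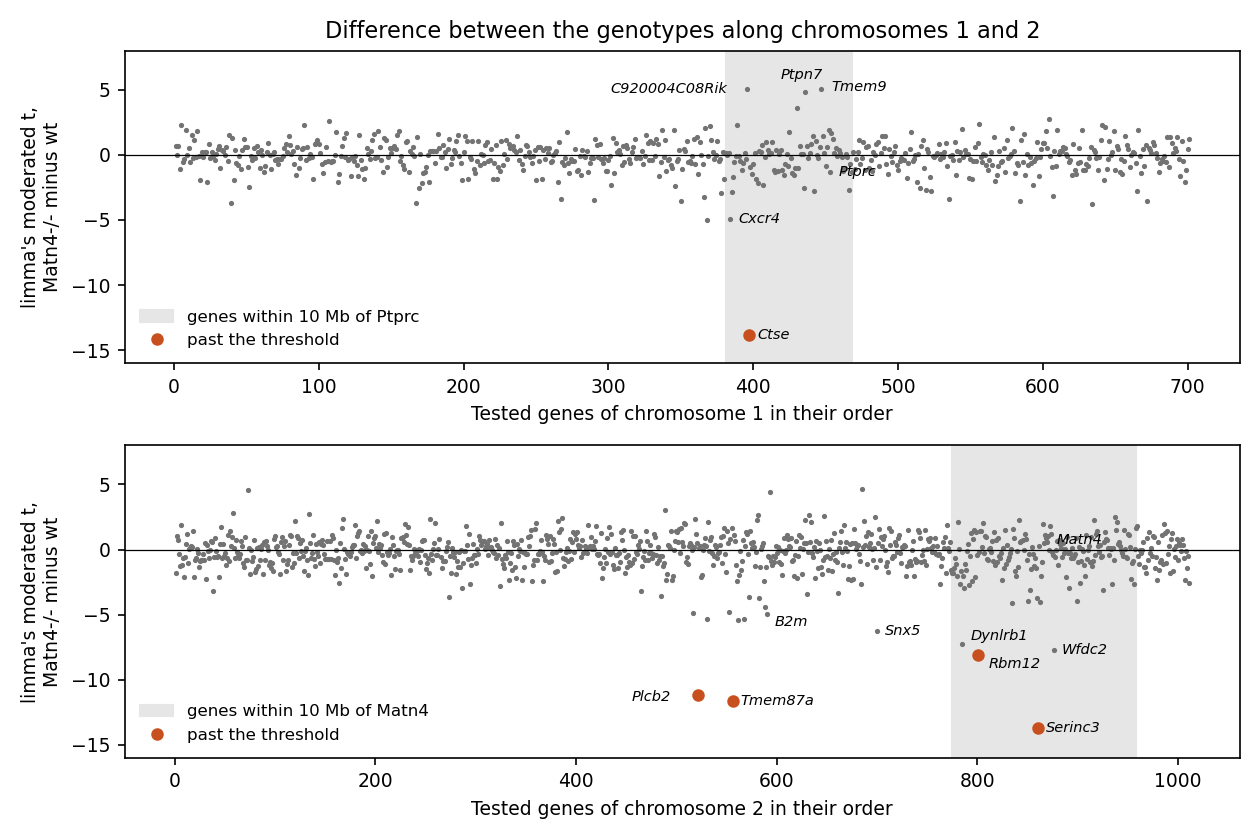
Moderated t of limma (Matn4-/- minus wt) of the tested genes of chromosomes 1 and 2 in gene order, with the genes within 10 Mb of Ptprc or Matn4 on a grey ground and genes past the threshold in orange. Negative points of chromosome 2 include Plcb2, Tmem87a, B2m and Snx5 outside the window and Rbm12, Dynlrb1, Serinc3 and Wfdc2 inside it, and C920004C08Rik stands high beside Ctse on chromosome 1.

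Matn4-/- replicate 3 stood apart from the other arrays. Its mean Spearman correlation with them was 0.745 over all probes, against 0.852 to 0.866 for the others. Over the dimmer 50% of probes it was 0.147 against 0.472 to 0.487, and over the brightest 11559 probes 0.844 against 0.847 to 0.872. Without that array 5 genes passed, each among the 7.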

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

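The gene-by-gene fits with an array left out were set beforehand. The prediction for genes 1 to 10 Mb from Matn4 was written before its result was seen. It rests on the comparison of shares, which was added after the data had been seen. All other tests in this part were chosen after the results had been seen. Of 11 probes past the threshold when each probe was tested alone, 3 carry no gene name in the platform table and enter no comparison above. All 3 were lower in cells labelled Matn4-/-, 1 at the level of Y-linked probes there and at least 1.56-fold higher in wt, the others with log2 fold changes of -1.68 and -0.71 (limma adjusted p-values of 0.0145, 0.0156 and 0.0159). The probe with the largest difference, ILMN_1225181, read 482 ± 44.7 in wt and 154 ± 42.9 in Matn4-/- cells (SD, n = 3 each).

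The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 7 genes, was the 1 split to do so, and the highest of the others gave 0.

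Genes near Matn4 were at an unadjusted p under 0.05 more often than others (odds ratio 2.44). Probe brightness, Matn4-/- replicate 3 and an effect limited to the next neighbours are argued against by 0.03% of 10000 brightness-matched sets holding as many, a ratio of 2.33 without that array and a ratio of 2.46 among genes 1 to 10 Mb away. Genes 1 to 10 Mb away hold 16 of the 21 genes at that p in the window, so their ratio largely restates the excess. DNA of another strain carried along with the deletion cannot be told apart from an effect of Matn4 loss on genes near Matn4. Every Matn4-/- array would carry both and no group separates them. Whether transcripts or single bases under the probes differ stays open, since 15 of 19 other kept probes of these genes went the same way, 6 of them at an unadjusted p under 0.05, and 10 of the 21 genes had no other kept probe. With each array left out the ratio lay between 2.00 and 2.72, which shows how steady the excess was and not its source.

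Genes near Ptprc, among them Ctse and Cxcr4, were also at that level more often (odds ratio 2.98). The brightness of the probes does not account for it, with 0.14% of matched sets as high. The excess depended on Matn4-/- replicate 3, with a ratio of 1.22 without that array (Fisher's exact p = 0.638). Why it did was not tested. DNA of another strain at the CD45 locus, which the wt donor carries in the CD45.1 form, cannot be told apart from loss of Matn4, because the donors differ in both. Without any other single array the ratio lay between 2.08 (without wt replicate 3, Fisher's exact p = 0.0906) and 3.54 (without wt replicate 2). Ctse passed without each of the arrays, and Cxcr4 was lower in each such fit.

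Matn4-/- replicate 3 differed from the others mostly among dim probes. Mature blood cells of every lineage, which would raise all their markers alike, stay open. The 7 lists of markers moved apart there over all 92 members (permutation p = 0.008, and 0.0319 without the mast cell list). Mast cells lay above the other 5 arrays (0.562, 95% interval over the list's members 0.153 to 0.97) and platelets below them (-0.0993, -0.184 to -0.0149). The intervals of the other 5 lists reached across 0. Over the 43 members above the brightest Y-linked probe the test did not pass (permutation p = 0.0846), which leaves the question undecided. Intervals and permutations treat the members of a list on 1 array as independent and do not measure the spread between arrays. Some lists outside the blood lineages, such as cholesterol and lipid synthesis, were lowest on that array too, and others were not. Less signal over background on that array may be the source, since over the brightest 11559 probes its correlation of 0.844 lay close to the lowest of the others, 0.847. The allowed gap of 0.02, the choice of 7 lists and the test between them, the last of several rules tried, were set with these values known. Mast cell transcripts, highest on that array, stay open as a separate difference. Their list rose with the replicate number in both genotypes, to 0.26 on wt replicate 3 and 0.47 on Matn4-/- replicate 3, so it was not particular to that array.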

How the results depend on the processing

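Over 115 results and 2173 alternative values, 2093 kept their direction and side of the threshold, 73 values that passed in neither fit differed in sign and are counted among these, and no setting moved the median of all genes beyond 0.0259 on the log2 scale. Several settings were chosen after the data were seen, namely older symbols joined, the brightest 11559 probes, probes above the brightest Y-linked probe and the genes outside both windows. Counts of genes were 3 to 7 with an array left out, 4 with older symbols joined, 3 without the genes near Matn4 and Ptprc (fewer genes tested) and 713 at an unadjusted p, and 5 to 9 under the other normalizations, filters and moderations, 10 at an adjusted p under 0.10. Ctse reversed to 0.63 with older symbols joined, since the clone-name probe C920004C08Rik then represents it, and Zfp87, which passed in neither, turned to 0.11 there in the same way. Rbm12 and Wdr73 lost their call in most settings. The number of lists past the threshold, 0 in the main setting, was 0 to 4 with an array left out (4 without wt replicate 3), 1 with the replicate block, quantile normalization, normexp, cyclic loess or the mean of probes, and 2 with the brightest 11559 probes or with probes above the brightest Y-linked probe. The Matn4 neighbours were called in 8 of 21 settings, the monocyte list in 3 of 22 (without wt replicate 3, the brightest 11559 probes, probes above the brightest Y-linked probe), the mast cell list in 2 (without wt replicate 3 or Matn4-/- replicate 1) and the erythroid list in 1 (without wt replicate 3). With an estimated correlation and all arrays, camera gave each of these lists an adjusted p of 0.795. The odds ratio near Ptprc was 1.22 to 3.54 with an array left out. The cause of these changes was not tested unless stated. Same-numbered arrays correlated at 0.017, 0.059 and 0.061 in their deviations from the group means, which neither shows nor excludes shared recipients. The replicate block gave 9 genes, 5 shared with the 7 and among the others Cxcr4 and Wfdc2, and was the only 1 of 18 settings to call Cxcr4 (adjusted p = 0.0276, up to 0.736 in the others), and 2 of 3 wt and 3 of 3 Matn4-/- arrays correlated best with their own number. Slide as a block and detection filters were not run. Background in the values limits dim genes, where Matn4-/- replicate 3 correlated with the others at 0.147.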

Other observations

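The test of bins was chosen after the positions had been seen. On chromosome 2 the genes at an unadjusted p under 0.001 continued well beyond the surroundings of Matn4. Whether DNA of another strain carried along with the deletion reaches that far cannot be told from these arrays. B2m, the light chain of class I histocompatibility molecules, read 1278 ± 188 in wt and 857 ± 52.4 in cells labelled Matn4-/- (SD, n = 3 each; log2 -0.57, limma adjusted p = 0.306). It lies in one 20 Mb bin with Tmem87a, Ccndbp1 (log2 -0.70) and Lrrc57 (at the level of Y-linked probes in Matn4-/- cells and at least 1.13-fold higher in wt), all lower, and Plcb2 and Rmdn3 (log2 -0.44, above those probes on 1 of 3 Matn4-/- arrays) share the bin before it. Of these only Tmem87a and Plcb2 passed over all genes. With the places of genes shuffled 10000 times over 142 bins, 9.59% of shuffles had a bin of 4 or more such genes. The bin edges were fixed, and one parts Plcb2 and Rmdn3 from Tmem87a, Ccndbp1, Lrrc57 and B2m, so the shuffles did not test these genes together. The fullest bin held 5 of 95 genes, Ctse, Cxcr4, Tmem9, 3110009E18Rik and C920004C08Rik on chromosome 1, and 1.23% of shuffles reached that. The gene table places the last of these at Ctse. With each gene of that table counted once (719 other names left out), the bin held 4 of 86 genes and 8.23% of shuffles had a bin as full.

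Markers of the myeloid lineages varied between arrays of one genotype. Mpo, the myeloperoxidase of early granulocytes, read 517, 621 and 858 on wt replicates 1 to 3 and 617, 534 and 1114 on Matn4-/- replicates 1 to 3. Neutrophil and granule genes were lowest on wt replicate 1 (-0.15) and highest on wt replicate 3 (0.13) and Matn4-/- replicate 3 (0.12), relative to their mean over the 6 arrays.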
